A study of Mus musculus with 2 samples.

How the data were processed

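Kidneys were digested with liberase and the filtered cell suspension was made into droplet-based 10x Chromium 3′ libraries, per the labels' protocols. The groups were defined by the treatment label, an isotype control antibody and an antibody against CSF1R, each with 1 library taken on day 42 from a group of 2 mice. Whether the mice of a group were pooled before loading is not given in the sources used here. The submitters' processing notes name Cell Ranger 3.1.0. Whether the lists fit that version and the library chemistry named in the labels is open, because neither the barcodes nor the genes could be checked against the lists that belong to them. The genome build, the gene annotation and the settings of the cell calling are not given in the sources used here.

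The files used, as deposited by the authors, were a list of cell barcodes and a list of genes for each library. The file names describe them as parts of a filtered matrix, which means that the authors' pipeline had already separated cells from empty droplets. These lists hold identities and not measurements, so no normalisation applied and no expression test could be run. Counts per gene and cell were not analysed here. The comparisons of cell type shares and of expression per cell type that had been planned for such counts were therefore not made, and the rule for naming genes by the size of their change was not used. Under that rule, genes were named without counts only as members of the gene lists fixed before the data were examined. The identifiers given in the text are for members that are central to the antibody's target or to macrophages, and for the symbol that replaced the missing one; these were picked after the lists had been seen. Doublets could not be assessed, and how the authors treated them is not given in the sources used here.

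Each line of a barcode list was counted as 1 called cell. The share of all barcodes in each library was given an exact Clopper-Pearson 95% interval, and the ratio of the libraries was derived from it. Barcodes were compared as 16-base sequences without their suffix. The number shared was given an exact Poisson 95% interval. The number expected by chance was the product of the library sizes divided by the number of combinations of first part, middle bases and last part that the observed parts allowed. The boundaries of the parts were chosen after the counts of distinct starts and ends had been seen. An expectation that treated the 16 positions as independent, planned before the data were examined, gave 0.156 shared barcodes and ignored these parts. Pairs 1 and 2 bases apart were counted exactly, and a count of 0 was taken to allow up to 3. Barcodes are not independent samples of a treatment, so these intervals describe the libraries and not the conditions. After the counts had been seen, 100 pairs of libraries of the real sizes were drawn evenly from the combinations, and the real parts were recombined at random within each library 100 times. A combination that arose more than once in a recombined library was kept once, so these libraries could be smaller than the real ones.

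Gene identifiers were matched without version to GENCODE M21, of which 32235 of the 32285 listed genes (99.8%) had an entry. Because the build of the files is not given, no coordinates are reported, and M21 was used only for gene classes. Symbols were taken from the files. The counting functions were tested on simulated barcode lists with planted shared and near-identical barcodes, and all 6 quantities were recovered exactly. Alternatives fixed before the data were examined concerned repeated sequences, neighbouring barcodes, shared barcodes, the distance at which barcodes count as near-identical, and symbols in place of identifiers. The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.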

Results

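The study profiled whole-kidney cell suspensions from C57BL/6 mice by droplet single-cell RNA sequencing, 42 days after a single injection of an antibody. One group received an antibody against CSF1R, the receptor for the growth factors CSF1 and IL-34 on which many tissue macrophages depend for survival. The other group received an isotype control antibody. The question, as the labels state it, was how the kidney changes over time after kidney-resident macrophages have been depleted. Each group had 2 mice and is represented by 1 library. Whether the cells of both mice were pooled in that library is not given in the labels. In either case there was 1 sample per group and no measure of the spread between animals. The values analysed here were the list of cell barcodes called as cells and the list of annotated genes in each library. Counts of transcripts per gene and cell were not analysed here, so no gene level, cell type share or effect of macrophage depletion on expression is reported. The depth of each library in transcripts is likewise not reported.

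The first comparison was the number of cells recovered from each treatment group. The control library held 24275 called cell barcodes and the anti-CSF1R library held 23140, a difference of 1135 barcodes. The ratio of anti-CSF1R to control was 0.953, with an exact binomial 95% interval of 0.936 to 0.971. The control library made up 51.2% of the 47415 barcodes (exact 95% interval 50.7 to 51.6%) and the anti-CSF1R library 48.8% (48.4 to 49.3%). These intervals cover counting error only. The number of cells recovered also depends on how many were loaded and on the cell-calling step, and with 1 library per group the difference has no replicate check. No test between the treatments was made. All barcodes of a library carried the same suffix, so the lists do not tell whether the number of cells in a library came from 1 mouse or from both. No cell could be assigned to the macrophages or to any other kidney cell type from its barcode.

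The second comparison was which genes each library was annotated for. Both libraries listed the same 32285 genes in the same order, all of the gene expression type, so no gene was annotated in one treatment group alone. The list contained Csf1r (ENSMUSG00000024621), which encodes the receptor the antibody targets, and its ligand genes Csf1 (ENSMUSG00000014599) and Il34 (ENSMUSG00000031750). It also contained Adgre1 (ENSMUSG00000004730), which encodes the macrophage surface protein F4/80, and Timd4 (ENSMUSG00000055546), a phosphatidylserine receptor of resident macrophages. All 130 entries of the 21 cell type marker lists fixed in advance were present. These lists included 17 macrophage, 9 monocyte, 8 dendritic cell and 5 neutrophil markers. They also included 10 proximal tubule markers, 8 markers of injured proximal tubule, 8 endothelial and 5 podocyte markers. Of the 57 entries in the 8 lists of response genes, 56 were present. The exception was Ctgf, in the fibrosis list, whose current symbol Ccn2 (ENSMUSG00000019997) was listed. Ccn2 was itself an entry of the fibrosis list, so this gene had been entered there under both symbols. Presence in the list says that a gene was annotated, not that it was detected in any cell.

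Some classes of transcript were outside the annotation in both libraries. Compared by identifier with GENCODE release M21 (GRCm38), the list held 21702 of 22028 protein-coding genes (98.5%) and 9830 of 10155 long noncoding genes (96.8%). It held 697 of 702 immunoglobulin and T cell receptor segments (99.3%), a class that here included the pseudogenes of those loci. It held 0 of 6115 genes for small and ribosomal RNAs and 6 of 13317 pseudogenes outside the immune receptor loci. The 13 protein-coding mitochondrial genes were listed, whereas 0 of the 2 mitochondrial ribosomal RNA genes were. A mitochondrial share of transcripts in these libraries would therefore count messenger RNAs only. A total of 78 genes carried 1 of 38 symbols that more than 1 identifier shared, and no member of the fixed lists was among them.

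The barcodes were then compared between the libraries, since a sequence present in both cannot identify a cell without the name of its library. The libraries had 158 barcode sequences in common (exact Poisson 95% interval 134 to 185), which was 0.651% of the control and 0.683% of the anti-CSF1R barcodes. Every barcode had 16 bases and was made of 3 parts. The first 7 bases took 3839 different sequences over both libraries and the last 7 bases also took 3839. The 2 bases between them, at positions 8 and 9 counted from the 5′ end, took 4 different sequences, and each first part and each last part occurred with only 1 of these. The observed parts allowed 3684480 combinations. Equal drawing from these combinations gave an expected 152 shared barcodes, within the interval of the observed number.

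**Figure D1:**
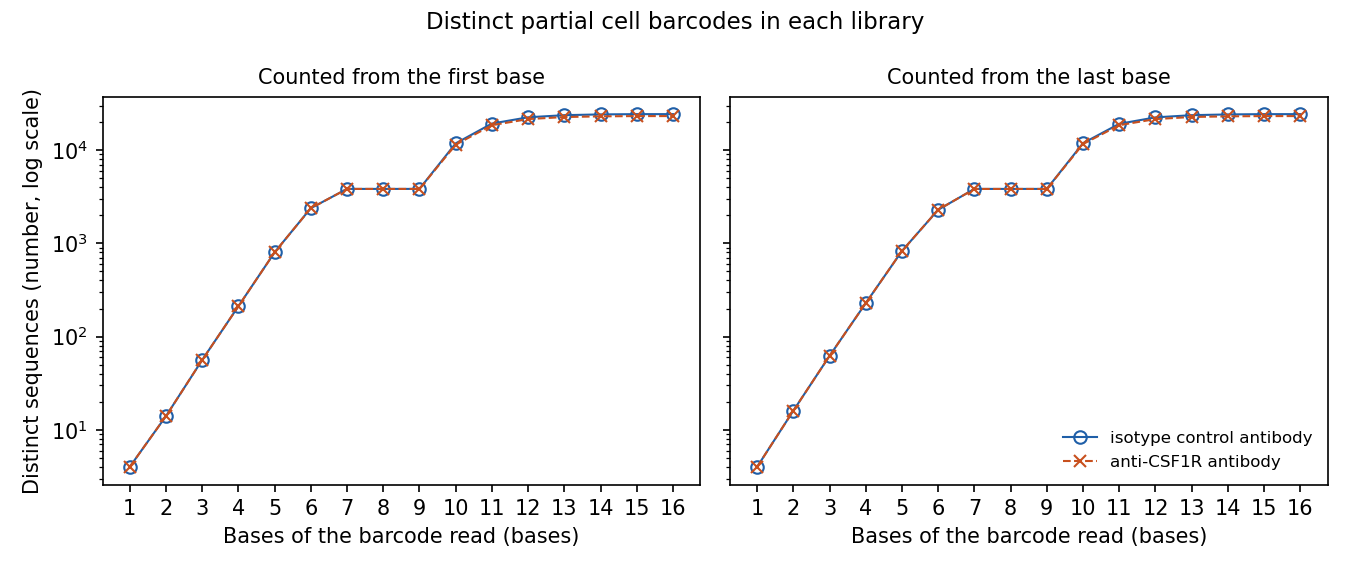
Number of distinct sequences (vertical axis, log scale) when only the first bases (left) or the last bases (right) of each cell barcode are read, by the number of bases read (horizontal axis). Circles with a solid line show the control library and crosses with a dashed line the anti-CSF1R library; both stay level from 7 to 9 bases, at 3832 distinct starts in the control and 3831 in the anti-CSF1R library.

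Barcodes that differ by a single base within a library can arise when errors split 1 cell into 2. No pair of barcodes 1 base apart was found among 294625675 possible pairs in the control library or 267718230 in the anti-CSF1R library, and none was found among 561723500 pairs across the libraries. Taken as a sample, a count of 0 would allow up to 0.0102 such pairs per 1000000 in the control and 0.0112 per 1000000 in the anti-CSF1R library. Parts that shared the same middle bases differed from each other at 2 or more positions, so the set of barcodes in use left no room for such pairs. The count of 0 was thus fixed, and it does not test whether errors split cells. The base composition of the barcodes was compared at each position. Over the 64 combinations of position and base, the largest difference was 1.03 percentage points, for C at position 3, with 27.1% in the control (exact 95% interval 26.6 to 27.7%) and 26.1% in the anti-CSF1R library (25.5 to 26.7%). The intervals of the libraries overlapped in every combination. Overlap is not a test of a difference, and no interval of the differences was computed, so equal composition is not shown.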

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

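Of 15 alternatives over 10 results, 6 could change nothing, since every sequence was already distinct, the barcodes had no neighbours 1 base apart and all cell type markers were present. They say nothing about stability. Another 5 left the value within a counting interval or within 1.5 times its size. For the expected number weighted by part frequency, that interval belonged to the observed shared barcodes and not to the expectation. Matching through older symbols left 56 response genes present, because it did not find Ctgf, and so it adds little about stability. Leaving out the barcodes found in both libraries gave 24117 control and 22982 anti-CSF1R barcodes. The other 4 changed what was counted. No barcode of the control library was the reverse complement of one in the anti-CSF1R library, 0 against the 158 shared as read. That 0 was fixed by the barcodes in use. Their middle bases were AG, CA, GT or TC, and the reverse complement of none of these was among them. It therefore also says nothing about stability. Allowing 2 differing bases in place of 1 gave 3396 pairs in the control library, 3157 in the anti-CSF1R library and 6935 across them. Counting symbols in place of identifiers gave 32245 distinct symbols for the 32285 listed genes. Chosen after seeing the data were the matching through older symbols, the expected number of shared barcodes itself (152), and its version weighted by part frequency (153). Other cell filters, clustering resolutions and expression means, chosen in advance, were not run, because counts per gene and cell were not analysed here. No paired analysis was possible because each group had 1 library. No library could be left out for the same reason.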

Other observations

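The counts of barcodes shared between the libraries and of pairs 2 bases apart were planned before the data were examined; the expected numbers, simulations and other tests in this part were chosen after the results had been seen. The 158 barcodes common to both libraries lay close to the 152 that independent draws from one pool would give (exact Poisson 95% interval of the observed number 134 to 185). Carry-over of material between the libraries as the source of most of them is argued against, since the excess over that number was at most 20.4% of the shared barcodes at the upper end of the interval. A smaller carry-over, of up to 32.2 called barcodes by the same bound, stays open, and transcript counts per barcode would be needed to test it. The lists hold only barcodes called as cells, so carry-over into barcodes that were not called would not be seen. No biological explanation was tested.

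Some properties of the barcodes lay outside 100 simulated even and independent draws. Across the libraries, 6935 pairs lay 2 bases apart, above the highest of 100 simulated even draws (6930; mean 6711 ± 86.5, SD). The first parts were used unevenly, with a variance over mean of 1.07 against at most 1.05 in the simulated draws. For the last parts it was 1.04, within the draws, with 3 of 100 as high. The middle bases also differed in use, from 5802 (GT) to 6263 barcodes (TC) in the control library. In the anti-CSF1R library they ranged from 5661 (GT) to 5943 (CA). The use of the middle bases was not compared with the simulated draws. Recombining the real parts gave at most 6916 pairs in 100 trials (mean 6677 ± 89.6, SD). Repeated combinations were kept once there, so the recombined libraries could be smaller than the real ones, which lowers the number of pairs. The narrow margin therefore does not decide whether uneven use of the barcode parts accounts for the observed number. Within the control library the 3396 pairs were below the simulated mean of 3523 ± 61.6 (SD), with 2 of 100 draws as low, and within the anti-CSF1R library the 3157 pairs were within the draws, with 24 of 100 as low. The margin of the number across the libraries over the highest even draw was narrow. Several quantities were compared, in simulations chosen after the results had been seen, and the control count ran the other way. Chance was therefore not excluded, and whether anything raised the number across the libraries stays open.

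As an approximation, if droplets drew their barcodes independently and evenly from the 3684480 combinations, 80.0 pairs of cells in the control library and 72.7 in the anti-CSF1R library would carry the same barcode by chance. That corresponds to 3.29 and 3.14 pairs per 1000 called barcodes. Such pairs would appear as 1 barcode each, and the lists alone do not show them. They would add to any doublets formed when 2 cells enter 1 droplet.

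The gene list differed from GENCODE M21 in 50 identifiers that M21 lacks, and 733 shared identifiers had another symbol. All 50 of these identifiers (100%) had a number above the highest in M21, and Ensembl numbers are assigned in sequence. A candidate explanation is an annotation release later than GENCODE M21. It would need more than 50% of them above that number, a threshold set after the results had been seen. The release itself was not determined.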
